A study of Homo sapiens with 18 samples.

How the data were processed

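The series holds large-RNA sequencing libraries from HEK293T cells, an established human embryonic kidney line, and from the extracellular vesicles (EVs) that these cells released. Per the labels' protocols, wild-type, ATG7-/- and ATG12-/- cells were kept without serum for 24 h, total RNA was isolated from EVs and cells with a NucleoSpin kit, and libraries were made with a stranded total-RNA kit, amplified for 22 cycles and read as single ends of 50 bases on a HiSeq4000. The labels put 18 libraries into 6 groups of 3, one group for each genotype in EVs and in cells, and call the members of a group biological replicates. The series text mentions separate lanes, but no label gives a lane or a date for a library, so no batch was modelled.

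The authors deposited 1 table of TPM values, a length-scaled share of each library, for 203027 transcripts in the 18 libraries, and each column sums to the same total by construction. The submitters' processing notes name Salmon 0.14 and DESeq2, with no role stated. The genome build, the annotation and the strand setting used for these values are not given in the sources used here. TPM keep no sequencing depth, so no counting interval or count test was possible, and the depth of each library is unknown. Because the values hold no counts, limma was used in place of the count test that had been named as the first choice. An exact 0 in such a table may be a failed estimate, so a gene at 0 is described as listed at 0, with each library's value.

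Transcripts were matched by identifier, without the version, to GENCODE release 29, whose coordinates are on GRCh38. The match found 202941 transcripts and missed 86, which held at most 0.038% of any library. Values were summed to 57865 genes. Coordinates given here come from that annotation, and not from the deposited table.

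Libraries were scaled by the median of ratios to a geometric-mean reference over genes with at least 1 TPM in every fitted library. Genes with at least 1 TPM in at least 3 of the fitted libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no replicate block. A fold change on this scale understates the change of genes with low values. The knockout comparisons in EVs were fitted on the 9 EV libraries, those in cells on the 9 cell libraries, and the EV-to-cell comparisons on all 18. The interaction tests asked whether the EV-to-cell difference was itself different in a knockout and in wild type. All p-values are from both-sided tests, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and are limma's unless another test is named. Errors of TPM are SDs over 3 libraries, and errors of log2 fold changes are limma's standard errors. Named TPM values are as deposited, before scaling.

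The samples of each group, the tests, the alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. The rule named ATG7 and ATG12 in every comparison. It then took up to 10 genes in each direction with the largest fold change among those past the threshold, with no overlap between the groups and at least 5 TPM in the higher group, leaving out clone-style names, pseudogene symbols and unnamed identifiers. For the interaction tests, overlap was read from differences of same-numbered EV and cell libraries, a pairing otherwise made only in the alternative with a block. From gene lists it took the members with the smallest p, at most 3 for a list that passed and 2 for another. The text prints only some of the genes the rule gave, chosen after their values were seen, and some results are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

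Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members. Camera asks whether a list's genes stand apart from all other genes, so a list can pass as higher while its own median is near or below 0. The same test with a correlation estimated from the residuals is given beside it. Shares of TPM by RNA class were compared with exact permutation tests, within genotypes for EVs against cells (8000 arrangements) and 3 against 3 between genotypes, where the smallest possible p is 0.1.

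The fits were tested on simulated data in which genes with a mean of at least 5 TPM were raised or lowered by known folds on the real levels and spread. Of 100 genes changed 2-fold, 0 were recovered in the ATG7-/- EV comparison and 0 in the ATG12-/- one. Of 100 changed 4-fold, 2 were recovered in each EV comparison, 41 in ATG7-/- cells, 34 in ATG12-/- cells and 8 between EVs and cells of wild type. The median fitted size was close to the true one each time (1.96 for a log2 change of 2 in ATG7-/- EVs). Among abundant genes changed 2-fold, 20 of 100 were recovered in ATG7-/- EVs, 21 of 100 in ATG12-/- EVs, 33 of 100 between EVs and cells of wild type, and 0 of 100 in the cells of either knockout. A low number of calls therefore does not show that few genes differed. Few genes were changed in each simulation, which makes the adjustment stricter than where many genes differ. The recovery between EVs and cells therefore does not give the share found in the real comparison.

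Alternatives were values without scaling, limma without the trend and with sample weights, other low-value filters, a pseudocount of 0.1, transcripts in place of genes, leaving out mitochondrially encoded and small noncoding RNA, fitting only the groups compared, the replicate number as a block, and leaving out each library in turn. In fits of all 18 libraries the block was each genotype and replicate number, which pairs same-numbered EV and cell libraries. Leaving out transcripts shorter than 200 nt was added after seeing the data, since short transcripts led many of the calls. Overlaps with genes on the opposite strand were computed with bedtools 2.31.1. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.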

Results

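RNA was measured in EVs and in cells of 3 HEK293T genotypes after 24 h without serum. ATG7 is the activating enzyme of the conjugation reactions that attach LC3 to membrane lipid, and ATG12 is the ubiquitin-like partner of ATG5 in the enzyme complex that completes the transfer. The comparisons below ask whether RNA in EVs differed without this LC3 conjugation machinery. Between 24209 and 31213 transcripts were above 0 in an EV library and between 37301 and 49040 in a cell library. Genes with at least 1 TPM numbered 13255 to 14716 in EVs and 18464 to 20509 in cells. The 10 most abundant transcripts held 25.12% to 28.92% of the TPM of an EV library and 22.49% to 25.72% of a cell library. Across genes, which are not independent replicates, the Pearson correlation of log2 values was 0.683 to 0.754 within an EV group, 0.763 to 0.837 within a cell group and 0.511 to 0.657 between an EV and a cell library. The first principal component held 32.9% of the variance and had the 9 EV libraries (-122 to -101) on one side and the 9 cell libraries on the other. On this axis the cells of ATG7-/- (79.4 to 117) and ATG12-/- (68.6 to 97.3) lay nearer the EVs than wild-type cells did (143 to 156). The median SD of a gene within a group was 0.58 to 0.68 log2 units in EVs and 0.40 to 0.47 in cells, so the EV comparisons had the larger replicate error.

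Many of the most abundant features lay opposite well-known mRNAs. AC006064.4, annotated on the strand opposite GAPDH, had 3490 ± 505 TPM in cells and 11700 ± 610 in EVs (SD, n = 9 each), while GAPDH itself had 84.7 ± 23.9 and 568 ± 110. AC011603.2, opposite the tubulin gene TUBA1B, had 4750 ± 1110 TPM in cells and 9290 ± 935 in EVs, against 34.5 ± 15.4 and 187 ± 34 for TUBA1B. SH3D19, which encodes an adaptor protein with SH3 domains, had 8320 ± 1640 TPM in cells and 36000 ± 9480 in EVs, and the ribosomal protein gene RPS3A 32.6 ± 13.2 and 256 ± 36.1. The leading SH3D19 transcript is 503 nt long, with 52.1% of it opposite exons of RPS3A. These features were chosen after their values were seen. The strand setting is not given. If it was set wrongly, every gene value printed here measures the opposite strand or stray reads, whether or not another gene is annotated there.

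The targeted genes were compared first. ATG7 (chromosome 3, 11272309 to 11557665, plus strand) had 15.6, 13.5 and 11.2 TPM in the EVs of ATG7-/- cells and 19.4, 14.9 and 13.3 in wild-type EVs. In cells it had 8.06, 11.2 and 12.9 TPM in ATG7-/- and 8.14, 11.1 and 13.1 in wild type. In ATG12-/- it had 13.8, 20.8 and 14.1 TPM in EVs and 14.9, 13.1 and 17.1 in cells. ATG12 (chromosome 5, 115828200 to 115841858, minus strand) had 0, 0.858 and 0 TPM in the EVs of ATG12-/- cells and 0.844, 9.54 and 22.6 in wild-type EVs. ATG12-/- cells had 6.71, 9.18 and 5.18 TPM of ATG12 and wild-type cells 10.1, 7.61 and 13.5. In ATG7-/- it had 12.2, 4.65 and 0.326 TPM in EVs and 11.9, 16.5 and 6.06 in cells. Neither gene passed the test against wild type in its own knockout (ATG7 log2 fold change -0.13, SE 0.47, adjusted p = 0.984 in EVs and 0.05, SE 0.27, adjusted p = 0.949 in cells; ATG12 -2.57, SE 1.1, adjusted p = 0.619 in EVs and -0.48, SE 0.38, adjusted p = 0.597 in cells). The labels do not give the kind of edit, and an edit that ends a protein need not lower its mRNA, so these values neither bear out nor contradict the labels.

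In EVs of ATG7-/- cells against wild-type EVs, the genes that rose included SH3D19 (chromosome 4, 151102751 to 151325632), from 23700 ± 1630 to 41300 ± 3020 TPM (SD, n = 3 in each group, log2 fold change 0.90, SE 0.08, adjusted p = 0.00271), and LHFPL3-AS2. The latter, a long noncoding RNA, rose from 6540 ± 904 to 12100 ± 543 TPM (0.99, SE 0.12, adjusted p = 0.0182). CDR1 (chromosome X, 140783578 to 140784366), the gene of a cerebellar degeneration antigen, rose from 370 ± 13.8 to 821 ± 47.5 TPM (1.24, SE 0.18, adjusted p = 0.0386). RPPH1 (chromosome 14, 20343075 to 20343407), the RNA of RNase P, fell from 11800 ± 1630 to 4220 ± 600 TPM (-1.39, SE 0.14, adjusted p = 0.00729). RN7SK (chromosome 6, 52995621 to 52995948), the RNA that holds the transcription elongation factor P-TEFb inactive, fell from 20700 ± 2830 to 9460 ± 1000 TPM (-1.03, SE 0.13, adjusted p = 0.0232). VIM-AS1, a noncoding gene with 69.8% of its main transcript opposite VIM, fell from 1820 to 806 TPM on average (-1.08, SE 0.15).

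In that comparison LIPT2, a mitochondrial lipoyl transferase whose signal lay mostly in a transcript of 218 nt, rose to 319, 131 and 281 TPM against 0, 0 and 1.64 in wild-type EVs. AVIL, the actin-binding protein advillin, rose from 1.74 ± 1.95 to 114 ± 37.9 TPM (log2 fold change 5.65, SE 0.80). SLC25A44, a mitochondrial carrier of branched-chain amino acids, fell from 107 ± 76.4 to 3.85 ± 1.49 TPM (-4.21, SE 0.60). Outside the rule, and chosen after their values were seen, AL138963.3, opposite the translation-controlled tumour protein gene TPT1, rose from 3140 ± 251 to 9020 ± 549 TPM (1.62, SE 0.11). So did the processed pseudogene AD000091.1, from 11500 ± 655 to 27000 ± 1050 TPM (1.33, SE 0.09), and AC067930.2, opposite the elongation factor gene EEF1D, from 832 ± 66.1 to 1740 ± 86.7 TPM (1.16, SE 0.15). A pseudogene shares reads with its parent gene and copies, so its value is uncertain.

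In total 24 of 17076 genes passed in ATG7-/- EVs, 17 higher and 7 lower, with 1265 at an unadjusted p under 0.05. Of the 24, 5 were protein-coding and 15 carried clone-style or pseudogene names. Over all genes tested, the groups did not overlap in 13.7%, where chance gives 10%. None of the 26 lists measured passed camera. The lysosome list of the TFEB network (32 genes, 20 lower, median log2 fold change -0.34, adjusted p = 0.176) and the list of endoplasmic reticulum chaperones and translocon (20 genes, 17 lower, median -0.29, adjusted p = 0.166) were below 0. So was the list of very long mRNAs, kept as a check of RNA length (19 genes, 14 lower, median -0.63, adjusted p = 0.176), while TOP mRNAs (95 genes, 57 higher, median 0.12) and nuclear-encoded respiratory chain genes (70 genes, 45 higher, median 0.28) were above 0 at the same adjusted p. The LC3 conjugation list (16 genes) had a median of -0.11, a mean of 0.13 and an adjusted p of 0.798. Leaving out wild-type EV replicate 1, 2 or 3 left 9, 15 or 12 genes. Leaving out ATG7-/- EV replicate 1, 2 or 3 left 5, 8 or 8. Without the trend and with sample weights, limma no longer called SH3D19 (adjusted p = 0.632), RPPH1 (0.457), AL138963.3 or AD000091.1, and 17 genes passed. SH3D19, RPPH1, AL138963.3 and AD000091.1 kept their calls with each single library left out.

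In EVs of ATG12-/- cells against wild-type EVs, SH3D19 again rose, to 42900 ± 2390 TPM (log2 fold change 0.93, SE 0.08, adjusted p = 0.0032), as did LHFPL3-AS2, to 11800 ± 129 TPM (0.93, SE 0.12, adjusted p = 0.0337). RPPH1 fell to 4560 ± 464 TPM (-1.30, SE 0.14, adjusted p = 0.014). MT-RNR2, the large ribosomal RNA of mitochondria (mitochondrial genome, 1671 to 3229), fell from 6620 ± 931 to 3330 ± 40.1 TPM (-0.91, SE 0.13, adjusted p = 0.0471). MT-TA, the mitochondrial alanine tRNA (mitochondrial genome, 5587 to 5655), was listed at 0 in the 3 ATG12-/- EV libraries and had 791, 3300 and 3640 TPM in wild-type EVs. KCNK1, a potassium channel, and FLJ46906, a noncoding RNA, were listed at 0 in wild-type EVs and had 26.2, 28.7 and 13.1 TPM and 14.5, 13.6 and 51.3 TPM in ATG12-/- EVs.

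HLA-DQB1-AS1, a noncoding RNA of the HLA region, rose from 0.255 ± 0.443 to 22.2 ± 9.25 TPM in ATG12-/- EVs (log2 fold change 4.18, SE 0.60), and NCAM1-AS1, opposite the adhesion molecule gene NCAM1, fell from 34.1 ± 13.1 to 0.38 ± 0.657 TPM (-4.61, SE 0.61). RN7SK had 10800 ± 1090 TPM and missed the threshold (-0.85, SE 0.13, adjusted p = 0.068), and so did CDR1 (1.13, SE 0.18, adjusted p = 0.0736). AL138963.3 (0.90, adjusted p = 0.033) and AD000091.1 (1.18, adjusted p = 0.00158), named after their values were seen, also rose. TOP mRNAs are those of ribosomal proteins and other parts of the translation machinery with a terminal pyrimidine tract. Their list passed camera as higher, with 61 of 95 members above 0 and none called (median 0.17, adjusted p = 0.00779; adjusted p = 0.207 with an estimated correlation). Its RPLP1 had 5630 ± 1470 against 1210 ± 518 TPM (2.35, adjusted p = 0.0801). Adjusted over the list alone, 4 members were higher. Mitochondrial rRNAs and tRNAs passed as lower, with 2 of 19 members called lower (median -1.43, adjusted p = 0.0034; adjusted p = 0.155 with an estimated correlation) and 3 lower adjusted over the list alone.

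In total 18 of 17076 genes passed in ATG12-/- EVs, 11 higher and 7 lower, with 1356 at an unadjusted p under 0.05 and no overlap between groups in 11.3% of all genes, where chance gives 10%. Only 2 were protein-coding. SH3D19, MT-TA and AD000091.1 kept their calls with each single library left out, but without the trend and with sample weights limma no longer called SH3D19 or AD000091.1. Of 11 named calls only MT-TA kept its call in every refit. Without the trend and with sample weights 4 genes passed, and 3 with the replicate number as a block. Leaving out wild-type EV replicate 1 or 3 left 7 or 10 genes, and leaving out ATG12-/- EV replicate 1 or 2 left 5 or 6. Without mitochondrially encoded and small noncoding RNA 8 passed.

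Both knockouts shared 7 called EV genes with the same sign, 5 higher and 2 lower, SH3D19, LHFPL3-AS2 and RPPH1 among them, and none with opposite signs. Both comparisons use the same wild-type libraries. In 100 simulations of unchanged groups against shared controls the mean overlap was 0.03 and the highest 1, and independent lists of these lengths would share 0.01095 higher and 0.00287 lower genes. Unchanged groups give hardly any calls to share (0 in the simulated data without a change). The simulated overlap was therefore bound to be near 0 and does not measure what the shared controls added. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.548 against 0.50 in simulation and a covariance of 0.707 against 0.457. With 3 wild-type libraries the controls could not be split, so part of the overlap may come from the shared controls. Without wild-type EV replicate 1 the overlap was 3.

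In ATG7-/- cells against wild-type cells, the more abundant named genes that rose were FMO1, a flavin monooxygenase, from 225 ± 3.58 to 481 ± 25 TPM (log2 fold change 1.16, SE 0.16, adjusted p = 0.0396), and NPDC1, a neural differentiation gene, from 48.8 ± 2.26 to 129 ± 17.1 TPM (1.45, SE 0.16, adjusted p = 0.0184). GK-AS1, a noncoding RNA opposite the glycerol kinase gene, rose from 37.5 ± 6.59 to 107 ± 5.62 TPM (1.57, SE 0.18, adjusted p = 0.0184). CD72, known as a receptor of B cells, rose from 11.3 ± 2.53 to 38.4 ± 1.22 TPM (1.76) and BCAS4 from 17.6 ± 3.66 to 65.9 ± 21.5 TPM (1.88). ADGRB1, an adhesion receptor, rose from 0.506 ± 0.272 to 5.5 ± 0.853 TPM (2.14) and GALNT1, an enzyme of O-glycosylation, from 0.913 ± 0.708 to 25.9 ± 9.59 TPM (3.84). SCAANT1, a noncoding RNA, was listed at 0 in wild-type cells and had 15.9, 41.5 and 33.0 TPM. It was the only one of these increases to keep its call with each single library left out.

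The microRNA precursor MIR215 had 150, 120 and 164 TPM and the H/ACA RNA SNORA49 128, 51.1 and 69.8 TPM in wild-type cells. Both were listed at 0 in all 6 knockout cell libraries and all 9 EV libraries. In ATG7-/- cells HOXB-AS4, a noncoding RNA of a HOX cluster, fell from 216 ± 94.3 to 4.09 ± 2.59 TPM (log2 fold change -5.34). There OSCP1 fell from 13.5 ± 1.65 to 0.382 ± 0.661 TPM (-3.43) and PIN4, a prolyl isomerase, from 44.6 ± 9.51 to 13.7 ± 1.48 TPM (-1.55). PIGQ, of the GPI anchor pathway, fell from 136 ± 38.8 to 9.0 ± 2.93 TPM (-3.71), a value that rests on a transcript of 187 nt. Without transcripts under 200 nt its fold change was 0.60 and not called.

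In total 45 of 22471 genes passed in ATG7-/- cells, 19 higher and 26 lower, with 3241 at an unadjusted p under 0.05 and no overlap between groups in 20% of all genes, where chance gives 10%. Of these 26 had a group listed at 0 throughout. Sterol synthesis genes passed camera as higher (17 of 20 members above 0, none called, median 0.51, adjusted p = 0.00846; adjusted p = 0.47 with an estimated correlation). The sterol enzyme SQLE, squalene epoxidase, had 39.4 ± 1.81 against 21.4 ± 5.06 TPM (0.94, adjusted p = 0.127), and 1 member was higher adjusted over the list alone. Replication-dependent histones (31 of 43 above 0, median 0.38, adjusted p = 0.0149), cell cycle genes (20 of 25, median 0.42, adjusted p = 0.0163) and TOP mRNAs (61 of 96, median 0.21, adjusted p = 0.0389) also passed as higher, with none called and none adjusted over the list alone. Each was lost with an estimated correlation (adjusted p = 0.55, 0.55 and 0.764). Leaving out wild-type cell replicate 1, 2 or 3 left 5, 24 or 11 called genes and leaving out ATG7-/- cell replicate 3 left 29.

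In ATG12-/- cells against wild-type cells, HYOU1, a chaperone of the endoplasmic reticulum (chromosome 11, 119044189 to 119057202), rose from 76.8 ± 7.43 to 205 ± 33.9 TPM (log2 fold change 1.43, SE 0.19, adjusted p = 0.0483). HDGF, a growth factor, rose from 52.1 ± 5.85 to 163 ± 11.3 TPM (1.66, SE 0.20, adjusted p = 0.0265) and the RNA helicase DHX9 from 34.0 ± 4.31 to 103 ± 10.9 TPM (1.61, SE 0.19, adjusted p = 0.0222). PFKFB2, a regulator of glycolysis with 57.2% of its main transcript opposite YOD1, rose from 144 ± 7.4 to 311 ± 22.3 TPM (1.14). The read-through transcript STAG3L5P-PVRIG2P-PILRB rose from 66.2 ± 4.5 to 178 ± 24.4 TPM (1.44). SFXN4, a mitochondrial protein, had 8.84, 7.99 and 4.57 TPM and was listed at 0 in wild-type cells.

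In total 30 of 22471 genes passed in ATG12-/- cells, 11 higher and 19 lower, with 3360 at an unadjusted p under 0.05 and no overlap between groups in 23.8% of all genes, where chance gives 10%. Of these 22 had a group listed at 0 throughout. Camera passed 12 lists, 10 as higher and 2 as lower, and none with an estimated correlation. Among them lysosomal genes had 29 of 33 members above 0 (median 0.60, adjusted p = 2.71e-05; adjusted p = 0.138 with an estimated correlation; none called or adjusted over the list alone). CLCN7, a chloride transporter of lysosomes, had 42.4 ± 1.43 against 22.3 ± 7.38 TPM (0.97, adjusted p = 0.155). Endoplasmic reticulum chaperones had 16 of 21 above 0 and HYOU1 as the 1 called member (median 0.44, adjusted p = 0.00261; adjusted p = 0.138 with an estimated correlation), and 2 were higher adjusted over the list alone. Sterol synthesis genes had 15 of 20 (median 0.73, adjusted p = 0.00135; adjusted p = 0.138 with an estimated correlation; 3 higher adjusted over the list alone, SQLE at 47.3 ± 0.845 TPM). TOP mRNAs had 81 of 96 (median 0.57, adjusted p = 1.94e-09; adjusted p = 0.22 with an estimated correlation; 3 higher adjusted over the list alone, RPS14 at 172 ± 47.7 against 60.2 ± 8.82 TPM). The other lists that passed as higher were histones (median 0.53, adjusted p = 9.21e-05), RNA-binding proteins linked to vesicle loading (0.51, 0.00262), cell cycle (0.40, 0.00252), ATF4 targets (0.50, 0.00389), neuronal and adrenal-lineage genes known in HEK293 cells (0.50, 0.0168) and vesicle biogenesis genes (0.39, 0.0213). Nuclear long noncoding RNAs (-0.43, 0.0354) and fibroblast matrix genes (-0.52, 0.0312) passed as lower. With an estimated correlation the adjusted p of these 8 lists was 0.164 to 0.342. All 10 lists that passed as higher here also passed as higher in EVs against cells of wild type, a comparison that shares the wild-type cell libraries. None of the members of these 8 lists was called, and adjusted over the list alone 1 histone, 1 vesicle biogenesis gene and 1 matrix gene passed. Leaving out wild-type cell replicate 2 or 3 left 13 or 14 called genes and leaving out wild-type cell replicate 1 left 18.

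The cells of both knockouts shared 14 called genes, all lower, MIR215 and SNORA49 among them, where simulated unchanged groups shared 0.01 on average and at most 1 and independent lists would share 0.02198 lower genes. Unchanged groups again give hardly any calls to share, so the simulated overlap does not measure what the shared controls added. Of the 14, 13 were listed at 0 in all 6 knockout libraries and had the same fold change in both, so this overlap rests on their values in wild type. The correlation of fold changes across genes was 0.565 against 0.501 in simulation and the covariance 0.439 against 0.236. Part of the overlap may come from the shared controls, and without wild-type cell replicate 1, 2 or 3 it was 1, 2 or 3 genes.

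EVs were then compared with the cells they came from, to describe which RNA the vesicles held. In wild type NET1, an exchange factor of RhoA (chromosome 10, 5412551 to 5458463), had 407 ± 72.5 TPM in EVs and 9.16 ± 4.8 in cells (SD, n = 3, log2 fold change 4.97, SE 0.34, adjusted p = 2.52e-07), and the small GTPase RAB13 (chromosome 1, 153981617 to 153986358) had 303 ± 7.44 and 7.77 ± 1.38 TPM (4.65, SE 0.27, adjusted p = 5.47e-08). ANP32B, a histone chaperone, had 400 ± 44 against 10.2 ± 3.01 TPM (4.71, SE 0.31), and STRADB, a pseudokinase partner of the kinase LKB1 with 18.7% of its main transcript opposite TRAK2, 545 ± 84 against 19.8 ± 2.66 (4.22, SE 0.27). The signal recognition particle RNA RN7SL3 (4.89, SE 1.63), SLC25A44 (4.42), the sorting nexin SNX8 (4.05) and TMEM219 (4.01) were also higher. RPL14 had 2340 ± 1060 against 116 ± 153 TPM (4.64, SE 0.95), but its main transcript is 170 nt long and without transcripts under 200 nt its fold change was -0.41 and not called. RN7SL copies are near-identical and share reads, so their separate values are uncertain.

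Mitochondrial RNA was lower in wild-type EVs. MT-ND6, MT-ND5 and MT-ND4, subunits of respiratory complex I, had 33.5 ± 7.61, 146 ± 18.9 and 136 ± 11.2 TPM in EVs and 1230 ± 400, 1270 ± 94.3 and 1000 ± 69.1 in cells (log2 fold changes -5.62, -3.61 and -3.38). Of 13 mitochondrial mRNAs 12 were called lower (median -3.38, adjusted p = 2.56e-13; adjusted p = 0.00246 with an estimated correlation; 12 lower adjusted over the list alone). Mitochondrial tRNAs for methionine and asparagine, MT-TM and MT-TN, were listed at 0 in the 3 EV libraries, where cells had 1670, 1480 and 1110 TPM and 907, 871 and 594 TPM. MT-TE fell from 6600 ± 3030 to 78.6 ± 89.3 TPM and MT-TW from 9780 ± 2060 to 361 ± 531 TPM. Of 23 mitochondrial rRNAs and tRNAs 12 were lower and 1 higher (median -3.47, adjusted p = 0.00163; adjusted p = 0.0112 with an estimated correlation; 13 lower and 1 higher adjusted over the list alone). MT-RNR2, named after its value was seen, was the higher one, at 6620 ± 931 against 2440 ± 336 TPM (0.94, SE 0.14, adjusted p = 0.000419). The microRNA precursors MIR5096 (1170, 745 and 555 TPM in cells) and MIR4273 (517, 207 and 282) were also listed at 0 in the 3 EV libraries. Such features are under 120 nt long, and TPM of very short transcripts are unstable.

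In wild type 6086 of 24647 genes passed between EVs and cells, 994 higher and 5092 lower, with 9504 at an unadjusted p under 0.05 and no overlap between groups in 38.0% of all genes, where chance gives 10%. Of the called genes 2725 were protein-coding and 2079 had a group listed at 0 throughout. The median log2 fold change of all genes was -0.75, and -0.476 without scaling. Without scaling 32.0% of the calls were higher, against 16.3% with it. Camera sets each list against that shifted median, and 19 of 29 lists passed. Protein-coding genes as a whole held 37.6% of the TPM of EV libraries on average and 23.3% of cell libraries. Lists were not set against other coding genes, so a list of mRNAs that passed as higher need not stand apart from them.

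TOP mRNAs formed the largest group higher in wild-type EVs, with 52 of 97 called higher and 1 lower (median 1.70, adjusted p = 1.32e-40; adjusted p = 0.00128 with an estimated correlation; 58 higher and 1 lower adjusted over the list alone). RPS4X had 2630 ± 49 against 212 ± 46.6 TPM, RPS14 825 ± 114 against 60.2 ± 8.82 and the elongation factor EEF2 22900 ± 2070 against 3280 ± 747. Of 9 RNA polymerase III transcripts 4 were higher (median 1.17, adjusted p = 0.000271), among them RPPH1, from 845 ± 219 to 11800 ± 1630 TPM (3.33), and RN7SL2, from 12200 ± 2670 to 54300 ± 4250 TPM (1.68). Of 50 replication-dependent histones 8 were higher (median 0.66, adjusted p = 7.81e-07), HIST2H2AA3 from 182 ± 53.6 to 1210 ± 180 TPM and HIST1H2BK from 45.9 ± 7.66 to 379 ± 94.5. Immediate early genes had 4 of 13 higher (median 1.17, adjusted p = 1.31e-05), with FOS at 39.5 ± 16.6 against 1.58 ± 0.763 TPM. Endoplasmic reticulum genes had 5 of 21 higher (median 0.61, adjusted p = 5.52e-06), with the translocon subunits SSR3 and SSR4 at log2 fold changes of 2.73 and 2.22. Each of these 5 lists also passed with an estimated correlation, and 4, 8, 4 and 8 members of the last 4 were higher adjusted over the list alone. If the strand was set wrongly, the coding values are stray reads, whose share may be larger in EVs. Over all genotypes GAPDH rose from 84.7 TPM in cells to 568 in EVs, and AC006064.4 opposite it from 3490 to 11700. KPNB1 rose from 65.4 to 130 TPM, while AC015674.1 opposite it fell from 9470 to 7570. These list results therefore do not establish vesicle cargo.

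More lists passed as higher in wild-type EVs, with an estimated correlation too. They were cell cycle genes (3 of 26 called, 2 over the list alone, median 0.92, adjusted p = 5.52e-06), ATF4 targets (4 higher and 1 lower of 19, median 0.54, adjusted p = 3.28e-05, SHMT2 at 1.84), lysosomal genes (5 higher and 1 lower of 33, 1 higher over the list alone, median 0.86, adjusted p = 8.11e-05) and autophagy initiation genes (3 higher and 1 lower of 19, median 0.48, adjusted p = 0.000455). Others were the LC3 conjugation list (2 higher and 1 lower of 16, median 0.41, adjusted p = 0.00336, with the LC3 relative GABARAP at 134 ± 16 against 28.4 ± 6.85 TPM), neuronal and adrenal-lineage genes (3 higher and 1 lower of 10, median 0.50, adjusted p = 0.00127) and sterol synthesis genes (2 higher and 2 lower of 20, median 0.17, adjusted p = 0.00173, INSIG1 at 2.00). Where no other count is given, the same number passed adjusted over the list alone. NRF2 targets (5 higher and 3 lower of 21, 5 and 4 over the list alone, median 0.10, adjusted p = 0.0104), vesicle-linked RNA-binding proteins (3 and 2 of 24, median 0, mean 0.12, adjusted p = 0.0209) and vesicle biogenesis genes (1 and 3 of 24, median 0.29, mean -0.02, adjusted p = 0.0153) passed with medians near 0, above that of all genes. Nuclear-encoded respiratory chain genes passed as higher (8 higher and 6 lower of 77, 8 and 5 over the list alone, adjusted p = 0.0117) although their median was -0.34 and their mean -0.33, since camera compares them with all genes. The list of very long mRNAs (2 higher and 3 lower of 19, median 0.21, mean -0.04, adjusted p = 0.0406) was the 1 list lost with an estimated correlation (adjusted p = 0.0503 with an estimated correlation). The lists that did not pass were autophagy receptors (median 0.16, mean -0.01, adjusted p = 0.109), small nuclear RNAs (1.25, -1.39, 0.21) and small nucleolar RNA host genes (0.12, -0.14, 0.0721), where mean and median differ in sign. Nor did H/ACA RNAs (median -2.45, adjusted p = 0.49), C/D RNAs (-0.37, 0.588), small Cajal body RNAs (-1.79, 0.472), nuclear long noncoding RNAs (-0.89, 0.589), interferon-stimulated genes (-0.84, 0.454), blood cell genes (-0.35, 0.784) and fibroblast matrix genes (-0.83, 0.684), and the test pointed up for the C/D RNAs and the blood cell genes. Plasma and liver genes had under 5 measured members in every comparison.

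In ATG7-/- 2809 genes passed between EVs and cells, 668 higher and 2141 lower, and in ATG12-/- 2752, 559 higher and 2193 lower, with 6926 and 6804 at an unadjusted p under 0.05. RAB13 had 464 ± 20 TPM in ATG7-/- EVs against 10.2 ± 3.75 in the cells (log2 fold change 5.21) and 649 ± 29.8 against 4.83 ± 1.59 in ATG12-/- (6.69). NET1 had fold changes of 5.24 and 5.08, STRADB 5.37 and 5.60 and TRAK2, an adaptor of the kinesin motor, 4.13 and 4.68. The kinesin KIF1C had 238 ± 19 against 9.49 ± 4.06 TPM in ATG7-/- (4.38), and OAZ2, an inhibitor of polyamine synthesis, was higher in ATG12-/- (4.47). RNA5S1, the smallest cytosolic ribosomal RNA, had 1130, 3200 and 3620 TPM in ATG7-/- EVs against 140, 0 and 0 in cells, and 9600, 4380 and 882 TPM in ATG12-/- EVs against 0 in the 3 cell libraries. It has many identical copies, so its value is uncertain. TOP mRNAs were called higher for 62 of 97 in ATG7-/- (median 1.92) and 52 of 97 in ATG12-/- (1.76), and mitochondrial mRNAs lower for 12 of 13 (-3.21) and 13 of 13 (-3.28). In these comparisons 17 and 16 lists passed, and 16 and 15 with an estimated correlation. ATG7 did not pass in any genotype (0.06, 0.10 and -0.05 in wild type, ATG7-/- and ATG12-/-), and ATG12 passed only in ATG12-/- (-2.67, SE 0.83, adjusted p = 0.0496; -0.95 and -1.51 in wild type and ATG7-/-), a call lost without any 1 of those 6 libraries. Leaving out ATG7-/- cell replicate 1 left 1546 calls, and leaving out ATG12-/- cell replicate 1, 2 or 3 left 1292, 1478 or 1734. Without scaling 34.4% of the ATG7-/- calls were higher, against 23.8% with it.

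The shares of TPM by RNA class followed the same division. Mitochondrially encoded RNA held 3.53% ± 1.13 of the TPM of EV libraries and 14.21% ± 1.52 of cell libraries (SD, n = 9 each, exact permutation p = 0.00025, the smallest that 8000 arrangements can give). Ribosomal protein mRNAs held 2.98% ± 0.44 and 0.51% ± 0.16 (exact p = 0.00025) and the 7SL, Y, vault, RMRP and RPPH1 RNAs 9.86% ± 1.23 and 3.03% ± 0.51 (exact p = 0.00025). Small nucleolar RNAs held 0.57% ± 0.19 and 0.92% ± 0.14 (exact p = 0.00025) and histone mRNAs 0.98% ± 0.11 and 0.58% ± 0.26 (exact p = 0.002). After adjustment over the 7 classes these stayed at 0.0028 or below. Histone mRNAs held 1.12% in EVs and 0.38% in cells of wild type and 0.94% and 0.51% in ATG7-/-. In ATG12-/- they held 0.89% and 0.86%, with overlapping libraries. Small Cajal body and small nuclear RNAs (2.43% ± 0.86 and 2.51% ± 0.28, exact p = 0.646) and all other genes (79.65% ± 2.75 and 78.23% ± 1.19, exact p = 0.0953) did not pass. These pooled values hide opposite differences. The former held 3.53% in EVs and 2.84% in cells of wild type, 1.71% and 2.45% in ATG7-/-, and 2.06% and 2.25% in ATG12-/-. All other genes held 76.27% and 78.14% in wild type, 80.64% and 77.67% in ATG7-/-, and 82.05% and 78.9% in ATG12-/-. Between EV genotypes, mitochondrial RNA held 4.69% ± 0.16 in wild type, 3.69% ± 0.60 in ATG7-/- and 2.20% ± 0.11 in ATG12-/-, and small Cajal body and small nuclear RNAs 3.53% ± 0.37, 1.71% ± 0.03 and 2.06% ± 0.08 (SD, n = 3). No library of either knockout overlapped wild type in these classes, and exact permutation p was 0.1 each time, the smallest that 3 against 3 allows. These classes do not stand out, since all 7 classes reached it in ATG12-/- EVs, and histone mRNAs and all other genes did so in ATG7-/- EVs too.

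**Figure D1:**
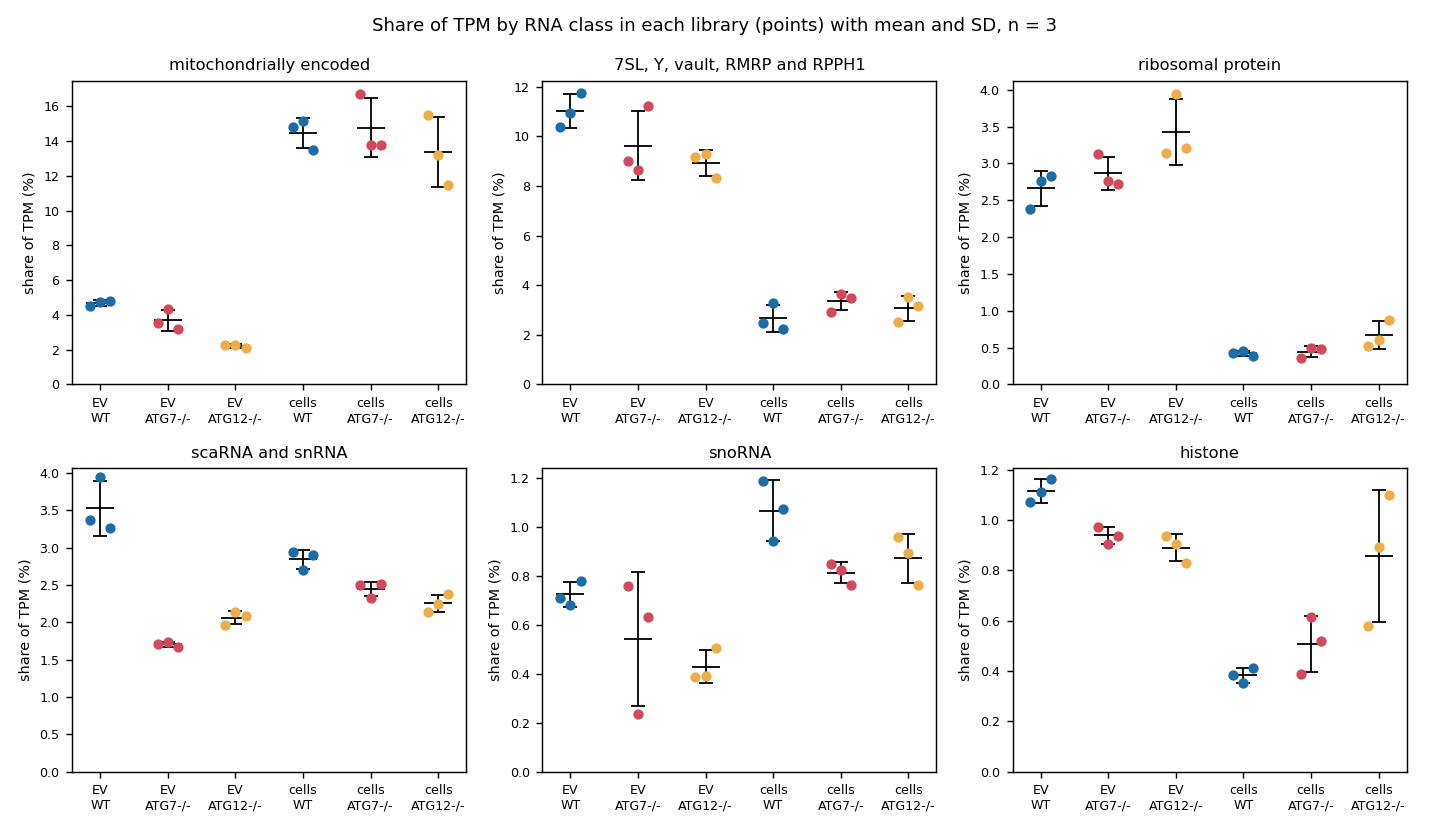
Share of TPM (%) of 6 RNA classes in each of the 18 libraries (points), with the mean and SD of each group of 3. Mitochondrially encoded RNA, mostly tRNA, lies between 2.08% and 4.81% in EV libraries and between 11.49% and 16.73% in cell libraries. The 7SL, Y, vault, RMRP and RPPH1 class lies between 8.33% and 11.75% in EV libraries and between 2.24% and 3.66% in cell libraries.

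**Figure D2:**
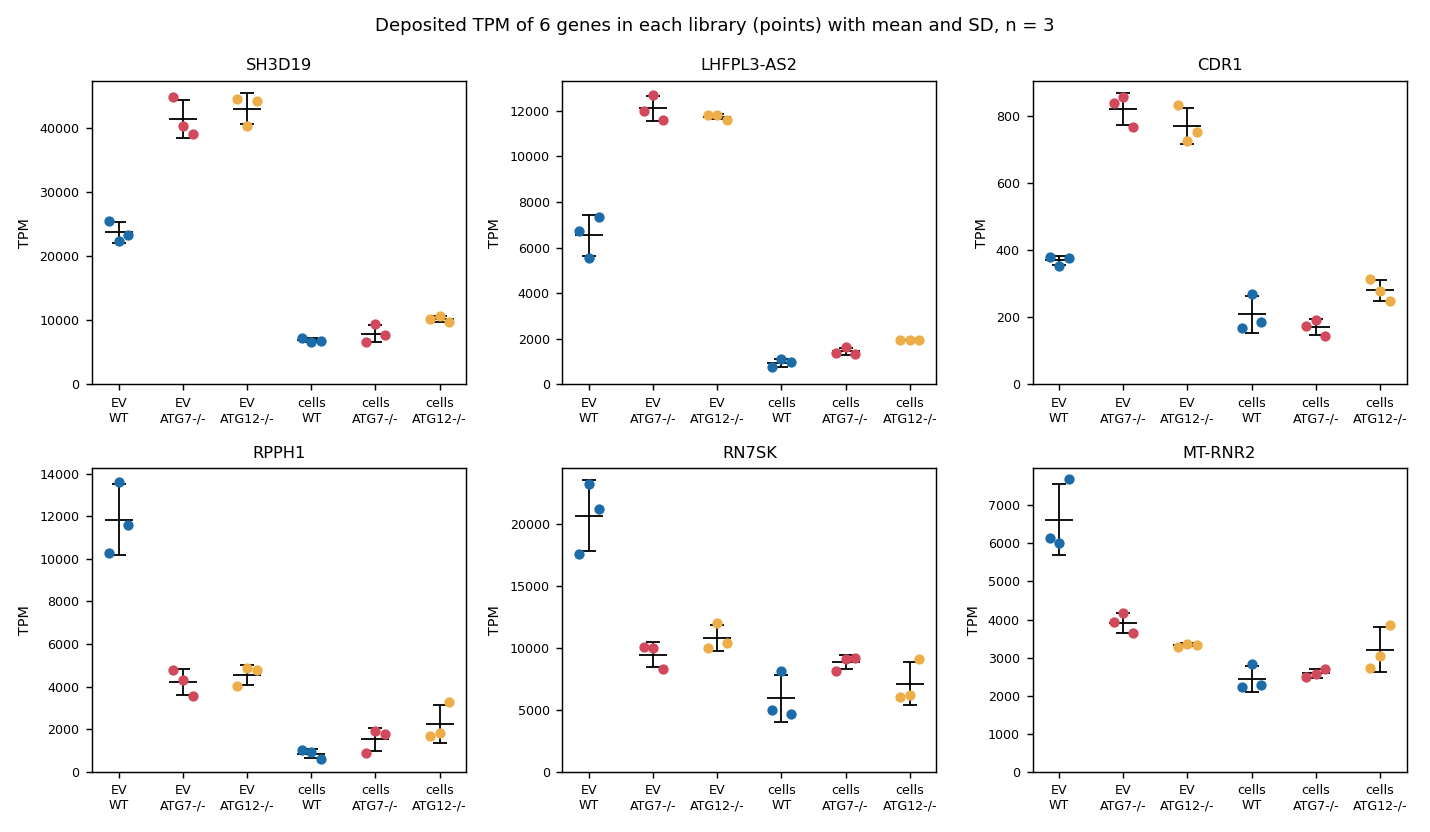
Deposited TPM of SH3D19, LHFPL3-AS2, CDR1, RPPH1, RN7SK and MT-RNR2 in each of the 18 libraries (points), with the mean and SD of each group of 3. RPPH1 lies between 10300 and 13600 TPM in the wild-type EV libraries and between 3570 and 4870 TPM in the EV libraries of the knockouts.

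The last comparison asked whether the EV-to-cell difference of a gene was itself different in a knockout. That difference moves with the level in cells as well as with that in EVs, so it does not isolate loading, and the knockout cells stood apart from wild-type cells towards EVs. In ATG7-/- it was lower for RPPH1 (EV 4220 ± 600 and cells 1530 ± 544 TPM in ATG7-/-, 11800 ± 1630 and 845 ± 219 in wild type, difference of log2 fold changes -2.03, SE 0.40, adjusted p = 0.0482), for RN7SK (-1.46, SE 0.28, adjusted p = 0.0423) and for SLC25A44 (-4.19). It was higher for CDR1 (1.69, SE 0.29, adjusted p = 0.0212), for APH1A, a subunit of gamma-secretase (2.18), and for ZNF90, a zinc finger gene (1.32). In ATG12-/- it was lower for RPPH1 (-2.39, SE 0.40, adjusted p = 0.0155), for MT-TA (-9.70), for SLC25A44 (-3.96), for the deacetylase SIRT1 (-3.25) and for the noncoding RNA LINC00273 (-1.33, SE 0.21). There it was higher for HINT3, a nucleotide hydrolase (3.19, SE 0.49, adjusted p = 0.01), for DHTKD1, a mitochondrial dehydrogenase (3.84), and for CCDC51 (2.76). SNORA49 and MIR215 passed as higher in both (6.52 and 7.41), but they were listed at 0 in every EV library, so these values reflect the cells alone. For RAB13, named after its value was seen, it was higher in ATG12-/- (2.03, SE 0.39, adjusted p = 0.038) and 0.56 in ATG7-/- (adjusted p = 0.721).

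In total 70 of 24647 genes passed in ATG7-/-, 55 higher and 15 lower, and 66 in ATG12-/-, 46 higher and 20 lower, with 2196 and 2501 at an unadjusted p under 0.05. With each cell library subtracted from the EV library of the same number, although the numbers may not pair them, the differences did not overlap in 13.4% and 14.4% of all genes, where chance gives 10%. Of the called genes 52 and 43 had a group listed at 0 throughout, and ATG7 (0.05 and -0.10) and ATG12 (-0.56 and -1.72) did not pass. Lysosomal genes were lower as a list in both (ATG7-/- 20 of 33 below 0, median -0.70, adjusted p = 0.00812; ATG12-/- 25 of 33, median -0.71, adjusted p = 0.00118), as were endoplasmic reticulum genes (16 of 21, median -0.52, adjusted p = 0.00951; 18 of 21, median -0.66, adjusted p = 0.00452). These 4 calls held with an estimated correlation (adjusted p = 0.0374, 0.0146, 0.0415 and 0.028 with an estimated correlation), and no member was called over all genes or adjusted over the list alone. In ATG7-/- the lysosomal protease CTSD had 39.4 ± 1.79 TPM in EVs and 46.1 ± 13.6 in cells against 71.7 ± 9.86 and 24.5 ± 8.87 in wild type (-1.47, adjusted p = 0.378). In ATG12-/- 4 more lists passed, and each was lost with an estimated correlation: mitochondrial rRNAs and tRNAs (median -0.75, adjusted p = 0.0155, then 0.0711; 1 called lower, 3 over the list alone), histones (-0.19, 0.0199, then 0.174; 2 lower over the list alone) and cell cycle genes (-0.32, 0.0291, then 0.157), all lower, and nuclear long noncoding RNAs (0.68, 0.0199, then 0.174; 1 higher over the list alone), higher. Leaving out wild-type cell replicate 1, 2 or 3 left 35, 38 or 26 genes in ATG7-/- and 34, 30 or 26 in ATG12-/-, and leaving out replicate 3 of the knockout cells left 43 in each. Without scaling 47.7% of the ATG12-/- calls were higher, against 69.7% with it, and 45 genes passed in ATG7-/-.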

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

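The tests of other splits of the libraries given here were chosen only after the results were seen. The results listed are those in which the EV-to-cell difference was different in a knockout and in wild type by a test of that difference.

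In ATG7-/- 70 genes passed that test and in ATG12-/- 66. The EV and the cell libraries of a genotype pair were regrouped separately, and 100 splits were drawn, the real one included. The real split called 70 genes in ATG7-/-, where the highest of the others called 147, and 66 in ATG12-/-, where the highest of the others called 84. In each case 2 of the 100 splits gave as many, a share under 0.05. A random division of libraries would thus seldom give these counts. The share was not adjusted for the 2 comparisons, which use the same wild-type libraries. An unlabelled batch that followed genotype would give the same counts, so they do not establish a genotype effect. Of the 2 splits, the one that was not the real one each time kept the genotypes apart and exchanged them in the cells only. It reads the change common to EVs and cells, so these counts do not show that genotype acted on the EV-to-cell difference more than on both. Splits that kept the genotypes of the cells apart and mixed those of the EVs called 35 to 59 genes in ATG7-/- and 35 to 65 in ATG12-/-. Those that kept the EVs and mixed the cells called 19 to 45 and 10 to 31. The counts thus went more with the genotype of the cells than with that of the EVs in ATG12-/-, while in ATG7-/- these ranges overlap.

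RPPH1 was lower in both (-2.03 in ATG7-/- and -2.39 in ATG12-/-), as was SLC25A44 (-4.19 and -3.96). SNORA49 (6.52 in both) and MIR215 (7.41 in both) differed through the cells alone. In ATG7-/- RN7SK was lower (-1.46), and AVIL (5.34), SNRPG, a core protein of spliceosomal particles (5.36), SSB, the La RNA-binding protein (4.05), APH1A (2.18), CDR1 (1.69) and ZNF90 (1.32) were higher. In ATG12-/- MT-TA (-9.70), CNTNAP3B (-4.49), the splicing factor WBP11 (-3.92), SIRT1 (-3.25) and LINC00273 (-1.33) were lower, and ATP5PO, a subunit of ATP synthase (7.92), DHTKD1 (3.84), HINT3 (3.19), CCDC51 (2.76) and RAB13 (2.03) were higher.

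The lysosomal list was lower in ATG7-/- (median -0.70) and in ATG12-/- (-0.71), and the endoplasmic reticulum list by -0.52 and -0.66. In the EV comparisons alone the medians of the lysosomal list were -0.34 and -0.32 and those of the endoplasmic reticulum list -0.29 and -0.30, none of which passed. In cells alone they were 0.20 and 0.60 for the lysosomal list and 0.44 and 0.44 for the endoplasmic reticulum list. Both lists passed in ATG12-/- cells (adjusted p = 2.71e-05 and 0.00261), though not with an estimated correlation (0.138 each), and neither in ATG7-/- cells (0.0834 and 0.0831), so in ATG12-/- the difference went at least as much with the cells. In ATG12-/- the test also passed for mitochondrial rRNAs and tRNAs (median -0.75), histones (-0.19), cell cycle genes (-0.32) and nuclear long noncoding RNAs (0.68), but not with an estimated correlation.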

How the results depend on the processing

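The tests without transcripts under 200 nt were chosen only after the results were seen. The 117 called results of named genes were refitted 1822 times, and 1312 refits kept direction and threshold, 508 kept the direction and lost the threshold, and 2 reversed. Over all refits 55 of the 117 kept both. With single libraries left out, 311 of 819 refits lost the threshold, and SH3D19, RPPH1, AL138963.3 and AD000091.1 were the 4 of 12 named EV calls in ATG7-/- that never did. In ATG12-/- EVs 3 of 11 never did, in ATG7-/- cells 4 of 14, in ATG12-/- cells 2 of 8, between EVs and cells 32 of 34 in wild type, 5 of 6 in ATG7-/- and 6 of 7 in ATG12-/-, and in the interactions 3 of 11 and 4 of 14. The 27 named results that were not called changed sign in 32 of 438 refits and passed in 4. PIGQ in ATG7-/- cells (0.60) and RPL14 between EVs and cells of wild type (-0.41) reversed without transcripts under 200 nt, which removes their main transcripts.

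Counts of calls moved as follows, and the cause was not tested except where fewer genes or libraries entered. In ATG7-/- EVs 24 became 8 without a low-value filter, 57 transcripts in place of genes and 14 with only the groups compared. In ATG12-/- EVs 18 became 5, 80 and 6 in the same way, 4 without the trend and with sample weights, and 8 without mitochondrially encoded and small noncoding RNA. In ATG7-/- cells 45 became 26 with at least 5 TPM and 129 transcripts, and in ATG12-/- cells 30 became 77 transcripts and 52 with only the groups compared. Between EVs and cells of wild type 6086 became 4049 with at least 5 TPM. In the interaction of ATG7-/- 70 became 45 as deposited, 27 without the trend and with sample weights, 32 with at least 5 TPM and 152 transcripts. In that of ATG12-/- 66 became 29 without the trend and with sample weights, and 146 transcripts. With an adjusted p of 0.10 the genes shared by both knockouts were 14 in EVs and 50 in cells. With an estimated correlation 0 lists passed in ATG12-/- EVs, 0 in ATG7-/- cells, 0 in ATG12-/- cells and 2 in the interaction of ATG12-/-. Leaving out scaling moved log2 fold changes by a median of 0.30 in wild type and 0.132 in ATG7-/- between EVs and cells, and by -0.178 and -0.247 in the interactions.

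Single libraries left out gave 5 to 15 calls in ATG7-/- EVs, 5 to 18 in ATG12-/- EVs, 5 to 48 in ATG7-/- cells and 13 to 30 in ATG12-/- cells. Between EVs and cells they gave 4339 to 5306 in wild type, 1546 to 2103 in ATG7-/- and 1292 to 2316 in ATG12-/-, and in the interactions 26 to 77 and 26 to 89. Both knockouts then shared 3 to 10 EV genes and 1 to 3 cell genes. Without mitochondrial genes in the total, the EV minus cell difference was -0.403 points for small Cajal body and small nuclear RNAs and -8.653 points for all other genes, and the difference of the latter between ATG12-/- and wild-type EVs was 3.881 points. Taking out a large class raises the share of the rest by construction. With single libraries left out the difference for all other genes was 1.179 to 1.642 points, and it passed without wild-type cell replicate 3 (exact p = 0.0418). On the 500 most variable genes the first component held 40.4% of the variance.

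The labels number the replicates alike, but same-numbered libraries did not deviate together (correlations -0.034 to 0.047). The numbers were therefore not taken as pairs in the main fits, although this does not exclude a common culture. With the replicate number as a block, the calls were 9 and 3 in the EVs of ATG7-/- and ATG12-/- and 13 and 12 in their cells. Genes shared by both were then 2 in EVs and 8 in cells. In the fits of all 18 libraries the block paired the same-numbered EV and cell library of a genotype. The calls were then 1407 and 1246 between EVs and cells of ATG7-/- and ATG12-/-, and 15 and 17 in the interactions. Depth is not known for any library, so what it limits could not be assessed.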

Other observations

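The tests of values assigned to the opposite strand by position, of scaling, of shared controls and of other splits, the MT-ND6 values of EVs, the levels of single antisense transcripts, the ratio of shares opposite introns and exons, the random lists, and the share of calls by the mean over both groups, were chosen only after the results were seen. The others here were written down first.

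By annotated type, protein-coding genes held 37.6% of the TPM of EV libraries on average and 23.3% of cell libraries, processed pseudogenes 6.4% and 4.3%, and antisense genes 16.7% and 17.9%. MicroRNA precursors held 3.1% and 11.3% and mitochondrial tRNAs 2.8% and 12%. These shares were not tested. MT-RNR2, the large mitochondrial ribosomal RNA, did not follow the other mitochondrial RNA. It had 6620 ± 931 TPM in wild-type EVs (SD, n = 3), 3920 ± 262 in ATG7-/- EVs and 3330 ± 40.1 in ATG12-/- EVs, against 2440 ± 336, 2590 ± 111 and 3210 ± 585 in the cells.

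Transcripts opposite coding exons often held more TPM than the genes' own strand. Among 498 coding genes with at least 5 TPM on either strand in cells, they did so for 75.7% in cells and 67.1% in EVs. Noncoding transcripts of at least 200 nt with at least 80.0% of their length opposite coding exons (748) had a median of 13.4 TPM in cells, where those on the same strand (261) had a median of 0, which is what values assigned to the strand opposite the RNA would give with a stranded kit. In the mitochondrial genome MT-ND6, the 1 mRNA of the other strand, was above the median of the other 12 mRNAs in 6 of 9 cell libraries, which decides neither way under a bound of 7, and below it in all 9 EV libraries, which goes against this explanation. Separate antisense transcripts retained in the nucleus would be lower in EVs than the genes opposite them, and over 281 pairs the median log2 fold change in wild type was -0.30 for antisense and 0.62 for host, with a median difference of -0.96 (bootstrap interval -1.29 to -0.77) and a Pearson correlation of 0.19 across pairs, which are not independent replicates. Under a wrong strand setting, however, the host values would be stray reads, whose share need not be the same in EVs and cells. This difference therefore does not separate the explanations. The median of all genes was -0.75, so these antisense transcripts were less lowered in EVs than a typical gene. Abundant ones such as AC006064.4 and SH3D19 were themselves higher in EVs than in cells, and both explanations stay open.

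Most genes called between EVs and cells of wild type, 5092 of 6086, were lower in EVs, and without scaling 68.0% of the calls still were. The scaling added here is therefore not the whole cause. Deposited TPM also sum to a fixed total, and what that total adds was not tested. Transcripts opposite introns, which measure unspliced nuclear RNA only if values were assigned to the opposite strand, held 7.35% to 10.5% of TPM in EVs and 6.82% to 9.66% in cells, and to take this overlap as exclusion, as first written down, was wrong by design while the strand is open. Relative to those opposite exons they were lower in every EV library than in any cell library of wild type (1.155 to 1.401 against 1.539 to 1.80) or ATG7-/- (0.825 to 0.864 against 0.960 to 1.228), but not of ATG12-/- (1.137 to 1.257 against 1.042 to 1.145), so unspliced nuclear RNA kept out of EVs cannot be told apart from the other explanations. If EV libraries sampled fewer low-level transcripts, under 60% of the calls among genes of at least 50 TPM should be lower, and by the level in wild-type cells, as first written down, 83.9% were, but that bound was wrong by design, since choosing genes by their level in cells favours genes lower in EVs. Taken by the mean over both groups, a choice made after that value was seen, 60.9% were lower (462 of 758, Wilson 95% interval 57.4 to 64.4), so thinner sampling and a difference in cargo cannot be told apart.

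The EVs of both knockouts shared 7 called genes, and the 3 wild-type EV libraries could not be split between the comparisons, so what the shared controls added cannot be told apart from a common effect. Among these genes SH3D19 and AL138963.3 lie opposite RPS3A and TPT1, and a candidate explanation is that mRNAs of the translation machinery were higher in knockout EVs and were read on the opposite strand. Only 2 other transcripts lay opposite genes of the translation list, against 1050 opposite other coding genes. Their medians were higher by 0.15 in ATG7-/- (exact permutation p = 0.847) and by 0.97 in ATG12-/- (exact permutation p = 0.277). A p under 0.05 in both had been asked for, and 2 transcripts are too few to decide. An effect of the loss of LC3 conjugation on these RNAs stays open and untested.

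RAB13, NET1, KIF1C and TRAK2, mRNAs known from other cells to localise to protrusions, were among the genes most raised in EVs (4.65, 4.97, 3.38 and 3.97 in wild type), which could mean that protrusion-localised mRNAs are enriched in EVs. Of 6 further mRNAs of that kind, listed before their values were looked at, 3 had a log2 fold change above 1 in wild type, RASSF3 (3.87), PKP4 (2.38) and CYB5R3 (1.04), where at least 4 had been asked for. DDR2 (1.00), DYNLL1 (0.60) and KANK2 (-1.18) did not. Their median of 1.02 was reached by 33 of 2000 random lists matched on level, whose median was -0.58. The random lists were drawn from all tested genes, noncoding ones included. Coding genes as a whole held 37.6% of the TPM in EVs and 23.3% in cells. The random lists therefore do not tell protrusion-localised mRNAs apart from other mRNAs. The protrusion hypothesis stays open.

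Splits of the 6 libraries of each comparison number 10, too few for a share under 0.05, and in each case 1 of the 10, the real one, gave as many calls. The real split called 24 genes in ATG7-/- EVs (highest other 10), 18 in ATG12-/- EVs (15), 45 in ATG7-/- cells (33) and 30 in ATG12-/- cells (17). Between EVs and cells it called 6086 in wild type (12), 2809 in ATG7-/- (10) and 2752 in ATG12-/- (5).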
